A study of Mus musculus with 6 samples.

How the data were processed

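Single-nucleus RNA sequencing was done on liver of wild-type (WT) mice and of mice labelled as Ifrd1 knockout (KO) at 0, 12 and 24 h after partial hepatectomy, the surgical removal of the median lobe and of the left lateral lobe, per the labels' protocols. There were 6 libraries, 1 for each genotype and time point. Nuclei were prepared with a commercial isolation kit and sequenced with droplet-based chemistry of 10x Genomics, per the labels' protocols. The deposited values were counts of unique molecular identifiers (UMIs) per gene and barcode, made with Cell Ranger. Its version was 6.1.0 per the file headers and 3.1.0 per the submitters' processing notes, which also give mouse genome build GRCm39. Whether intronic reads were counted is not stated in the sources used here. The smallest total of a barcode was 500 UMIs in 4 libraries and 503 UMIs in the other two.

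The 0 h libraries belonged to another series of library names than the later ones and were counted against another list of genes. That list held 34097 gene identifiers at 0 h and 33904 at 12 and 24 h. Of these, 33821 identifiers were shared and were used here, 276 were present only at 0 h and 83 only at 12 and 24 h. Among the shared identifiers, 1301 carried another symbol in each list, and they were joined by identifier. The shared identifiers held 99.7% of the UMIs in the WT and 99.6% in the KO-labelled library at 0 h and over 99.9% in the others. Any difference between 0 h and a later time therefore cannot be told apart from the library series, the gene list and the lower total depth at 0 h. UMIs per nucleus alone are argued against in hepatocyte-like nuclei, on an axis from the mean of 0 h (0) to 24 h WT (1). The third of 0 h nuclei with the most UMIs lay at -0.034 (WT, median 6646 UMIs) and 0.003 (KO-labelled, 4362). The third of 12 h nuclei with the fewest lay at 0.953 (WT, 3504) and 0.880 (KO-labelled, 4398).

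Barcodes with fewer than 500 detected genes or over 10% mitochondrial UMIs were removed, and doublets were called in each library with Scrublet (expected rate 0.06, scanpy 1.11.5). The automatic doublet threshold failed in the 12 h WT library, where it lay at 0.634 and called 0 doublets, so the median of the other thresholds, 0.157, was used there. Of 70033 barcodes, 60100.0 nuclei were kept. Counts were scaled per nucleus, 2000 variable genes were chosen, and 30 principal components were used without integration of the libraries. A graph of shared nearest neighbours (15 neighbours) was clustered with the Leiden method at resolution 1 (igraph 0.11.9). This gave 32 clusters. Many of them came almost wholly from 1 library. In hepatocyte-like nuclei, doublets included, cluster 0 held 4081 of 4149 from WT at 0 h, cluster 18 held 3969 of 4079 from the 0 h KO-labelled and cluster 15 held 3557 of 3632 from the 24 h KO-labelled library. The endothelial-like cluster 19 held 1646 of 1787 from the 24 h KO-labelled library. Clusters with over 50% called doublets were set aside as mixed, which held for 9 clusters. The other clusters were named from fixed marker genes where the best marker score was at least 0.25 and at least 2 times the second best, and where markers of another type did not outnumber its own among its 10 leading genes. A cluster with few detected markers, or with shallow nuclei and no own marker among its leading genes, was also to be left unnamed. The shallow endothelial-like cluster 20 had 2 own markers there, and 0 when genes were ranked with 5 CPM added in place of 1. Thresholds for naming clusters were set after the data had been seen. This left 2 clusters unnamed, numbered 4, which missed the score rule, and 13, which passed it (0.665 against 0.248) but missed the rule on leading genes.

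Counts were summed per library and class of nuclei. Hepatocyte-like, endothelial-like, macrophage-like and stellate cell-like nuclei were tested, as chosen before the data were examined, and every library held at least 20 nuclei of each. T or NK cell-like nuclei (70.0 to 299 per library), cholangiocyte-like nuclei (31 to 68) and cluster 13 (52 to 374) also reached 20 but were not tested. Genes were kept by filterByExpr and scaled by the trimmed mean of M values (TMM). All 6 libraries entered 1 robust quasi-likelihood fit in edgeR 4.0.16 with time and genotype as factors, which left 2 residual degrees of freedom. The genotype contrast is the mean of KO minus WT over the 3 time points, and each time contrast compares 2 libraries with 2 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and edgeR gave every adjusted p of a single gene. The tests, gene lists, marker genes and alternatives for the hepatocyte contrasts and for genotype in the other classes were written before the data were examined. Time contrasts in the other classes were added afterwards.

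Within a time point each genotype has 1 library, so no test was made. Counts scaled to the UMI total of the class (CPM) are given with exact Poisson intervals at 95% confidence, ratios of CPM with exact binomial intervals, and shares of nuclei with exact Clopper-Pearson intervals. These intervals cover counting error only. Gene lists within a time point are described by the median log2 ratio (prior of 1 CPM) over members of at least 5 CPM. Its percentile comes from 10000 random lists matched in 20 bins of mean expression.

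Gene lists across libraries were tested with camera (limma 3.58.1) on voom values at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Voom values, and separate adjustment of the fixed lists and the marker lists, were settled after earlier results had been seen. Camera with an estimated correlation and fry were run as alternatives. For each list, members past the threshold are counted with p adjusted over all genes and with p adjusted over the list alone.

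Genes named in the text follow a rule. In hepatocytes these are the 10 genes with the largest change in each direction among those past the threshold, with a mean of at least 20 CPM and the same direction in every pair. Where fewer than 5 genes passed, the 5 with the smallest p in each direction are given as values, and in other classes 3 in each direction. Predicted loci were left out, and loci named only by an identifier were left out after the values had been seen. Within a time point, the 5 genes with the largest ratio in each direction were taken, with at least 50.0 CPM in 1 library and at least 20 UMIs in both. Members of gene lists, Ifrd1 and sex-linked genes are named in addition. Some genes that the rule selects are not reported here.

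Cycling nuclei were counted after every hepatocyte-like nucleus was thinned to 1500 UMIs, as those with at least 2 UMIs in genes of G2 and mitosis. Alternatives were size factors of DESeq2 in place of TMM, no filter on low counts, the DESeq2 1.42.0 Wald test, at least 1000.0 genes per nucleus, at most 2% mitochondrial UMIs, and called doublets kept. Models without time or genotype, leaving out libraries, and Leiden resolutions of 0.5 and 2 were also run.

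The edgeR step was tested on simulated counts in which 200 genes were changed by a known fold. Each other gene had the same mean in all libraries, with no effect of time and no genotype difference that changed with time. Only genes with a mean of at least 5 CPM were changed. The shares recovered hold for that setting and may not carry over to the real counts. In hepatocyte-like nuclei the genotype contrast recovered 0% of genes changed 2-fold, 73.0% of those changed 4-fold and 98.5% of those changed 8-fold. The contrast of 12 h against 0 h recovered 0%, 16.5% and 89.0%. At 8-fold, 18 and 20 unchanged genes were called in these contrasts, beside 197 and 178 changed genes. At 4-fold, 14 and 7 unchanged genes were called beside 146 and 33 changed genes. In each of these settings the share of false calls lay above the threshold set for the adjusted p. At 2-fold, 0 unchanged genes were called in both contrasts. In the genotype contrast at 4-fold, 86.0% were recovered in endothelial-like, 80.5% in macrophage-like and 90.0% in stellate cell-like nuclei. The common biological coefficient of variation was 0.429 in hepatocyte-like nuclei. Calculations used Python 3.11.15 and R 4.3.3. The order of genes around Ifrd1 was taken from an annotation of build GRCm38, which is not the build of the files, and no coordinates were used.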

Results

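The study asks how Ifrd1 acts on gene expression while the mouse liver regrows after partial hepatectomy, with hepatocyte metabolism and macrophages at its centre. RNA in single nuclei was counted in 1 library for each of 6 groups, WT and KO-labelled liver at 0, 12 and 24 h after surgery. There are no replicates within a group, and the labels do not name separate animals for each library. The p-values therefore rest on the spread between libraries that is left after time and genotype. That spread holds library noise together with any genotype difference that changes with time, and the fit cannot separate them. WT libraries held 39090559 UMIs at 0 h, 86137662 at 12 h and 70255146 at 24 h. KO-labelled libraries held 28898601, 75555636 and 75878586 UMIs. Nuclei kept numbered 10211, 12321 and 8117 in WT and 9809, 9491 and 10151 in the KO-labelled libraries, in the same order of time. Median UMIs per nucleus kept ranged from 1917 in the 0 h KO-labelled library to 6086 in the 24 h WT library. Summed hepatocyte-like counts ranged from 17708354 UMIs at 0 h, KO-labelled, to 63942941 at 12 h, WT. Every library was male by its transcripts, with Ddx3y at 85.4 to 165 CPM and Xist at 0 to 1.20 CPM in hepatocyte-like nuclei.

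Ifrd1 (ENSMUSG00000001627) was read first, as a check on the labels. In hepatocyte-like nuclei it stood at 133 CPM in WT and 135 CPM in the KO-labelled library at 0 h, a ratio of 1.01 (0.962 to 1.07). At 12 h it stood at 314 CPM in WT and 226 CPM in the KO-labelled library, a ratio of 0.720 (0.704 to 0.736). At 24 h the values were 319 and 170.2 CPM, a ratio of 0.533 (0.519 to 0.547). Endothelial-like nuclei had ratios of 1.04, 0.473 and 0.648 at 0, 12 and 24 h, and macrophage-like nuclei 1.18, 0.737 and 0.568. In stellate cell-like nuclei the ratios were 0.927, 0.801 and 0.529. Averaged over time, the edgeR estimate in hepatocyte-like nuclei was a log2 change of -0.41 with adjusted p = 0.821. Ifrd1 was thus lower in the KO-labelled libraries at 12 and 24 h but not at 0 h in hepatocyte-like nuclei, and each library is called by its label. Which part of the gene was deleted is not stated in the sources used here, and UMIs from outside that part check nothing.

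**Figure D1:**
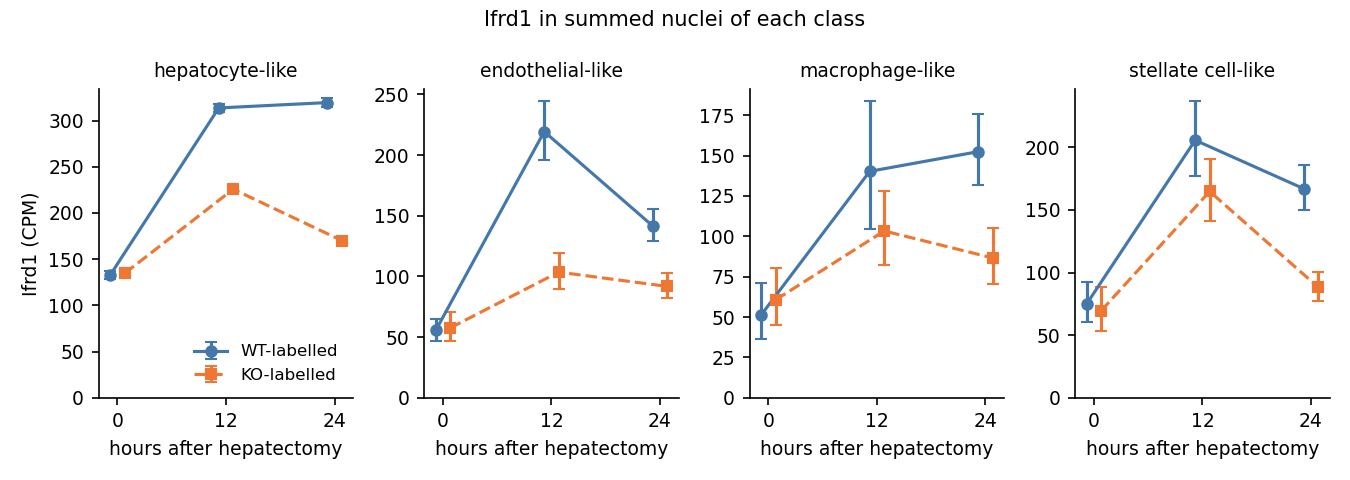
Ifrd1 in CPM per library in each class of nuclei, with exact Poisson intervals as bars and genotype by colour along time after surgery. In hepatocyte-like nuclei WT and KO-labelled values lie at 133 and 135 CPM at 0 h and at 319 and 170.2 CPM at 24 h.

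The comparison of 12 h with 0 h covers the first hours after surgery, and it cannot be told apart from the library series. In hepatocyte-like nuclei the acute phase genes Saa1, Saa2 and Orm1 rose by 12 h, while the steroid dehydrogenase gene Hsd3b3 and the glycogen genes Pygl and Gys2 fell. Saa2, which encodes a serum amyloid A protein, rose from 26.5 CPM in WT and 97.52 CPM in the KO-labelled library to 4179 and 2991 CPM, a log2 change of 5.97 (adjusted p = 0.0296). Osmr, which encodes the oncostatin M receptor subunit, rose by 5.33 (adjusted p = 0.0296), and the lipid droplet gene Plin4 by 6.52 (adjusted p = 0.0351). Hsd3b3 fell from 998 and 883 CPM to 9.01 and 30.4 CPM, a log2 change of -6.25 (adjusted p = 0.0382). The transcription factor gene Onecut1 changed by -5.84 (adjusted p = 0.0382), Pklr, which encodes the liver pyruvate kinase, by -5.25 (adjusted p = 0.0362), and the receptor gene Erbb4 by -4.87 (adjusted p = 0.0381).

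Other genes that rose most were Bmper (log2 6.92, adjusted p = 0.036), Nid1 (5.66, adjusted p = 0.0361), Sox5os4 (5.33, adjusted p = 0.0454) and Mybl1 (4.80, adjusted p = 0.0382). Syt12 rose by 4.68 (adjusted p = 0.0296), Kcnab1 by 4.58 (adjusted p = 0.0299) and Tnfrsf12a, a receptor gene of the tumour necrosis factor family, by 4.55 (adjusted p = 0.0449). Among those that fell were Hsd3b2 (-6.73, adjusted p = 0.0395), Apol9b (-5.40, adjusted p = 0.0296), Syt1 (-5.13, adjusted p = 0.0296) and Sdr9c7 (-5.01, adjusted p = 0.0449). Cish, which encodes an inhibitor of cytokine signalling, fell by 4.71 (adjusted p = 0.0447), and the carboxylesterase gene Ces3b fell by 4.64 (adjusted p = 0.0296). In all, 156 genes rose and 226 fell among 17934 tested, with 2 libraries at each time. In the simulated counts the share of false calls in this contrast lay above the set threshold at 4-fold and 8-fold changes. DESeq2 called 1426 and 1379 genes. The edgeR count of 382 depends on the libraries. It was 217 without the 0 h KO-labelled library and 116 without the 12 h WT library. It was 0 without the 0 h WT library, where 3606 genes had an unadjusted p under 0.05, and 0 without the 12 h KO-labelled library, where 2339 had. It was 2319 of 18839 tested without the 24 h KO-labelled library, which belongs to neither time compared but enters the gene filter, the scaling, the genotype term and the estimate of the spread.

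**Figure D2:**
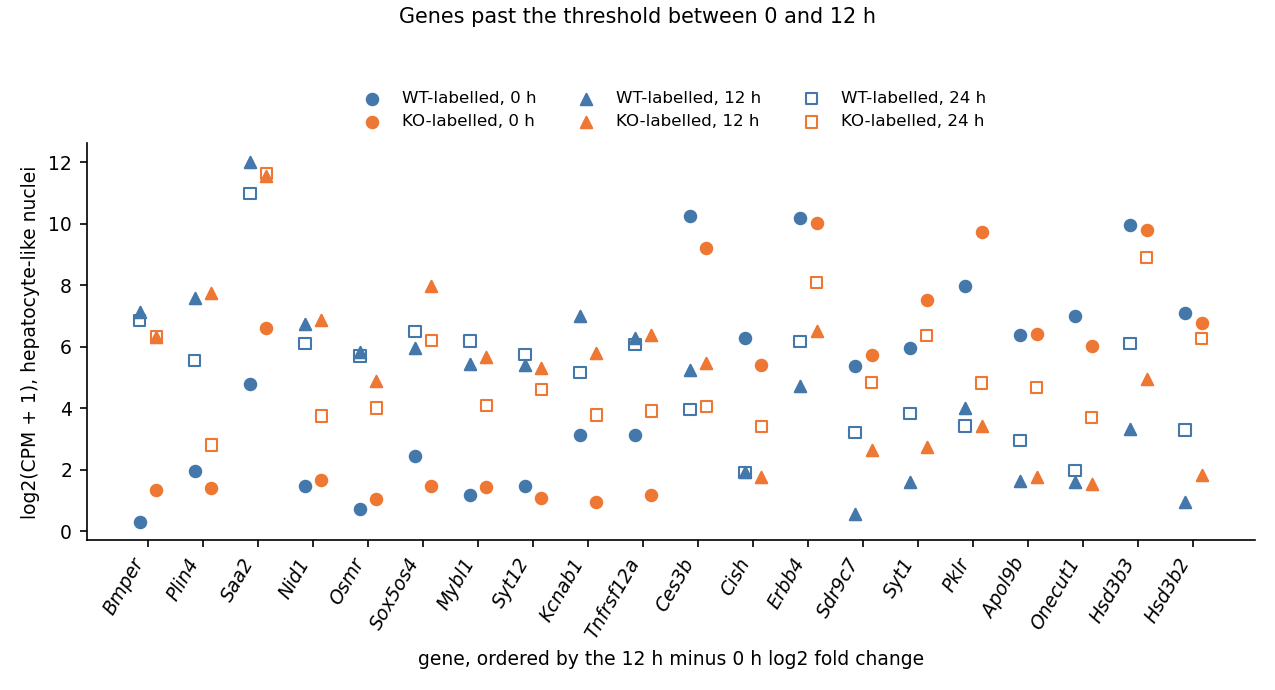
Values as log2 of CPM + 1 in hepatocyte-like nuclei of each library, with genotype by colour and time by symbol, for the named genes that passed the threshold between 0 and 12 h. Saa2 rose from 26.5 and 97.52 CPM to 4179 and 2991 CPM, and Ces3b fell from 1216 and 595 CPM to 36.8 and 43.2 CPM in WT and KO-labelled libraries.

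As groups, acute phase genes were higher at 12 h in 23 of 29 members, with a median log2 change of 1.04 (camera adjusted p = 4.3e-05, and adjusted p = 0.41 with an estimated correlation). Of these, 3 members, Saa1, Saa2 and Orm1, rose over all genes and 12 rose when adjusted over the list alone. Genes of glucose metabolism were lower in 20 of 24 members, with a median of -0.67 (adjusted p = 9.0e-05, and adjusted p = 0.41 with an estimated correlation). Pygl, which encodes liver glycogen phosphorylase, changed by -3.59 (adjusted p = 0.0296), the liver glycogen synthase gene Gys2 by -2.39 (adjusted p = 0.0382) and Pdk2 by -2.73 (adjusted p = 0.0362). With Pklr, 4 of these genes fell over all genes and 6 adjusted over the list alone. Periportal genes had a median of -2.00 and pericentral genes a median of -1.54, with 12 of 17 and 14 of 18 members lower. Their camera adjusted p were 0.0006 and 0.0034, and adjusted p = 0.41 and 0.72 with an estimated correlation. Among genes of amino acid metabolism, Gls2 changed by -2.79 (adjusted p = 0.036) and Got1 by -2.66 (adjusted p = 0.0454). Genes of the unfolded protein response were higher in 17 of 22 members, with a median of 0.79, 0 over all genes and 7 adjusted over the list alone (adjusted p = 0.0031, and adjusted p = 0.41 with an estimated correlation). Genes of DNA replication were higher in 18 of 34 members and camera gave adjusted p = 0.64. Within this list Ccne1 rose by 3.98 (adjusted p = 0.0464) and Mcm10 fell by 4.20 (adjusted p = 0.0473).

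Single genes of lipid metabolism changed in both directions by 12 h, and nothing is drawn from them about lipid genes as a group. The triglyceride synthesis gene Dgat2 changed by -2.83 (adjusted p = 0.0296), the transcription factor genes Mlxipl by -3.51 (adjusted p = 0.0404) and Ppara by -2.35 (adjusted p = 0.0464), and Pnpla3 by -4.27 (adjusted p = 0.0464). Cyp4a14 rose by 3.59 (adjusted p = 0.0454) and Angptl4 by 2.93 (adjusted p = 0.0296). The bile acid transporter gene Slc10a1 fell by 2.91 (adjusted p = 0.0419) and the cytokine receptor gene Lifr by 4.48 (adjusted p = 0.0415). Markers of other cell types were also lower at 12 h in hepatocyte-like nuclei. The median was -1.58 for sinusoidal endothelial markers (adjusted p = 0.0015), -1.26 for macrophage markers (adjusted p = 0.0062) and -2.63 for B or plasma cell markers (adjusted p = 0.0015), each with adjusted p = 0.41 with an estimated correlation. Because both 0 h libraries come from another library series with lower depth, time and series cannot be told apart here.

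Between 12 and 24 h, within 1 library series, the comparison covers the approach to DNA replication. Genes of DNA replication and of cholesterol synthesis were higher as groups at 24 h in hepatocyte-like nuclei by camera, each with adjusted p = 0.56 with an estimated correlation. Uhrf1, which helps to copy DNA methylation, stood at 0.110 and 0.0353 CPM at 12 h in WT and KO-labelled libraries and at 3.39 and 4.93 CPM at 24 h, a log2 value of 5.91 (adjusted p = 0.251). Mcm6, which encodes a subunit of the replicative helicase, stood at 3.47 and 3.23 CPM at 12 h and at 14.9 and 28.6 CPM at 24 h (log2 2.69, adjusted p = 0.32). Hmgcs1, an enzyme gene of cholesterol synthesis, stood at 70.0 and 136 CPM at 12 h and at 499 and 474 CPM at 24 h (log2 2.35, adjusted p = 0.261).

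Genes of DNA replication were higher in 32 of 34 members with a median of 1.75 (camera adjusted p = 2.6e-18, and adjusted p = 0.56 with an estimated correlation), 0 over all genes and 20 adjusted over the list alone. Only 16 members of this list reached a mean of at least 5 CPM over the libraries, so the other members rest on low counts. Genes of cholesterol synthesis were higher in 20 of 20 members with a median of 1.93 (adjusted p = 1.2e-23, and adjusted p = 0.56 with an estimated correlation), 0 over all genes and 19 adjusted over the list alone. Cyp51 had a log2 value of 2.61, Sc5d of 2.47 and Idi1 of 2.29. Genes of G2 and mitosis were higher in 28 of 33 members with a median of 1.501 (adjusted p = 3.3e-09, and adjusted p = 0.56 with an estimated correlation). Among them Top2a stood at 1.20 and 0.370 CPM at 12 h and at 7.60 and 9.56 CPM at 24 h. Immediate early genes were lower in 17 of 20 members with a median of -0.84 (adjusted p = 0.00038, and adjusted p = 0.56 with an estimated correlation). Pericentral genes had a median of 1.16 (adjusted p = 0.00021, and adjusted p = 0.56 with an estimated correlation). Mitochondrially encoded and nuclear-retained RNAs, a measure of RNA quality, were lower in 11 of 12 members (median -0.41, adjusted p = 0.02475, and adjusted p = 0.56 with an estimated correlation). From 12 to 24 h the median log2 ratio of immediate early genes was -0.10 in WT and -1.64 in the KO-labelled libraries, and that of pericentral genes 0.16 and 1.93, with no test of a difference between genotypes.

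No single gene passed the threshold in edgeR between 12 and 24 h, where 0 of 17934 genes were called, 1479 had an unadjusted p under 0.05, and DESeq2 called 292 higher and 111 lower. The smallest p belonged to Cyp2d13, at 15.9 and 25.5 CPM at 12 h and 239 and 536 CPM at 24 h (log2 4.18, adjusted p = 0.126). Higher at 24 h were also Zfp395 (3.39), Sord (3.06), Slc47a1 (2.96) and Acsl3 (2.64), each with adjusted p = 0.251. Lower were Scd1 (-2.14, adjusted p = 0.283), H3f3b (-2.07, adjusted p = 0.304), Actg1 (-1.68, adjusted p = 0.32), Cyp4a12b (-2.63, adjusted p = 0.326) and Greb1l (-1.72, adjusted p = 0.34). Without the 24 h WT library 287 genes were called, without the 24 h KO-labelled library 107, and without the 12 h KO-labelled library 1.

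**Figure D3:**
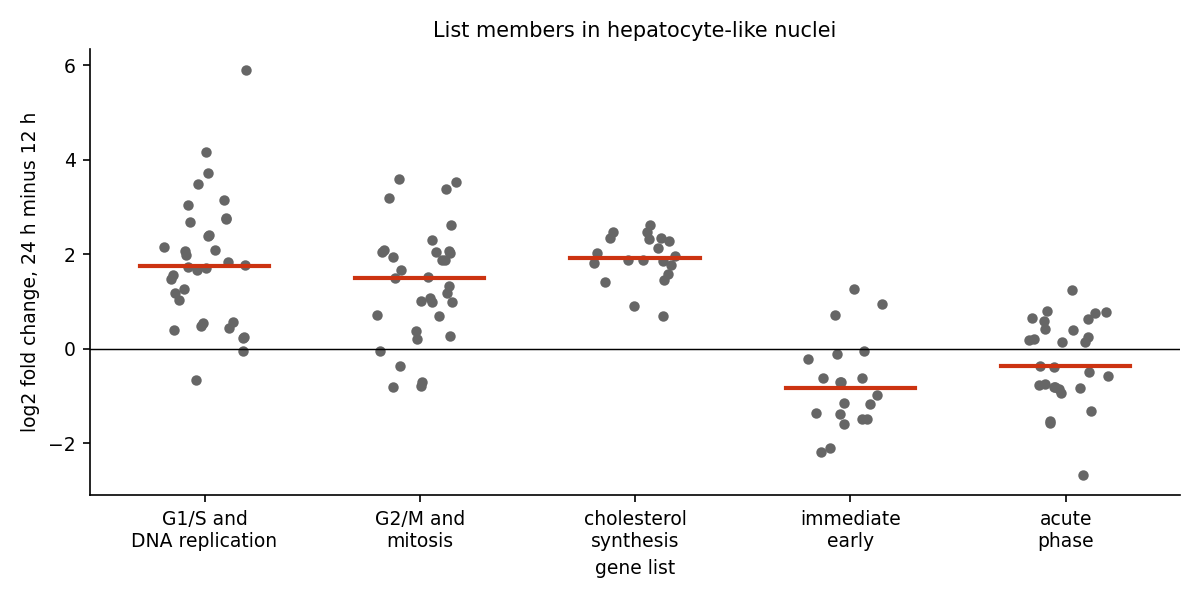
Log2 change from 12 to 24 h in hepatocyte-like nuclei for each member of 5 gene lists, with 1 point per gene and the list's median as a horizontal bar. Medians are 1.75 for DNA replication, 1.501 for G2 and mitosis, 1.93 for cholesterol synthesis, -0.84 for immediate early and -0.36 for acute phase genes.

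Between 0 and 24 h, DNA replication and cholesterol synthesis genes were again higher as groups by camera, and male-biased liver genes were lower, each with adjusted p = 0.45 with an estimated correlation. Genes of DNA replication were higher in 30 of 34 members with a median of 1.91 (camera adjusted p = 1.3e-10, and adjusted p = 0.45 with an estimated correlation). Here too, only 16 members of the list had a mean of at least 5 CPM. Genes of cholesterol synthesis were higher in 17 of 20 members with a median of 1.44 (adjusted p = 4.5e-09, and adjusted p = 0.45 with an estimated correlation), 0 over all genes and 13 adjusted over the list alone. Male-biased genes were lower in 13 of 13 members with a median of -2.61 (adjusted p = 1.3e-10, and adjusted p = 0.45 with an estimated correlation), 0 over all genes and 8 adjusted over the list alone. Elovl3 stood at 215 CPM in WT and 33.3 CPM in the KO-labelled library at 0 h and at 9.12 and 11.4 CPM at 24 h. Cyp2c40, from the fixed list of female-biased liver genes, was lower too, at 499 and 22.4 CPM at 0 h and 2.95 and 6.09 CPM at 24 h. Cyp2c69 of the same list stood at 210.1 and 12.5 CPM and at 0.289 and 5.01 CPM. A loss particular to male-biased genes is therefore not read from this. Ces3b stood at 1216 and 595 CPM at 0 h and at 14.5 and 15.8 CPM at 24 h (log2 -6.02, adjusted p = 0.0922), and Syt12 at 1.76 and 1.13 CPM and at 53.1 and 23.5 CPM (log2 4.50, adjusted p = 0.0922).

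Other genes with the smallest p from 0 to 24 h were Saa2 (log2 5.40), Osmr (4.88), Nrg1 (4.03), Mid1 (2.67), Sult5a1 (-3.80), Pygl (-3.27) and Upp2 (-2.83), each with adjusted p = 0.128, and Sntg2 (-2.49, adjusted p = 0.14). In edgeR 0 of 17934 genes were called, 2269 had an unadjusted p under 0.05, and DESeq2 called 548 higher and 376 lower. Without the 24 h KO-labelled library 856 genes were called, and without the 24 h WT library 73. Sinusoidal endothelial markers in hepatocyte-like nuclei were lower as well, with a median of -1.05 (camera adjusted p = 0.00023), as were B or plasma cell markers (-2.38, adjusted p = 0.00016), each with adjusted p = 0.38 with an estimated correlation. Library series and time cannot be told apart in this comparison either.

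The genotype comparison asks what differs between KO-labelled and WT livers on average over the 3 time points. In hepatocyte-like nuclei no gene passed the threshold. The smallest p belonged to Chrm3, which encodes a muscarinic receptor. It stood at 91.9, 19.7 and 48.6 CPM in WT at 0, 12 and 24 h and at 502, 197 and 349 CPM in the KO-labelled libraries (log2 2.92, SE 0.32, adjusted p = 0.249). Ripor2 stood at 42.0, 14.2 and 74.0 CPM in WT and at 256, 69.4 and 293 CPM in the KO-labelled libraries (log2 2.34, SE 0.27, adjusted p = 0.249). Lower in the KO-labelled library at every time was Gria3, a glutamate receptor gene, at 152, 62.6 and 44.9 CPM in WT and 22.1, 29.1 and 7.74 CPM in the KO-labelled libraries (log2 -2.10, SE 0.40, adjusted p = 0.59).

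Also higher in the KO-labelled library at all 3 times were Fam47e (log2 2.36), Rtn4rl1 (2.28) and Bcar3 (1.79), each with adjusted p = 0.517. Also lower were Igf2bp3 (-1.73), Ier2 (-1.24) and Ivns1abp (-1.18), each with adjusted p = 0.59. In edgeR 0 of 17934 genes were called, 1106 had an unadjusted p under 0.05, and DESeq2 called 149 higher and 38 lower. Without the 24 h KO-labelled library edgeR called 40 higher and 11 lower.

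As groups, pericentral genes were higher in the KO-labelled libraries in 17 of 18 members, with a median log2 difference of 0.95 (camera adjusted p = 5.0e-08, and adjusted p = 0.63 with an estimated correlation), 0 over all genes and 4 adjusted over the list alone. Within the time points their median log2 ratio was 0.95 at 0 h, -0.23 at 12 h and 2.48 at 24 h, so 12 h went the other way. Lgr5, a receptor gene of the Wnt pathway, stood at 30.1, 3.44 and 13.3 CPM in WT at 0, 12 and 24 h and at 93.3, 8.504 and 226 CPM in the KO-labelled libraries (log2 2.33, adjusted p = 0.68). Tbx3 had a log2 value of 1.94 (adjusted p = 0.599), Axin2 of 2.02 (adjusted p = 0.68) and Rnf43 of 1.43 (adjusted p = 0.672). Genes of cholesterol synthesis were higher in 20 of 20 members with a median of 0.57 (adjusted p = 7.6e-06, and adjusted p = 0.63 with an estimated correlation), 0 adjusted over the list alone. Their median was 1.165 at 0 h, 0.67 at 12 h and -0.15 at 24 h. The 24 h value lay near the median of all genes there (-0.16) and changed sign with TMM scaling, so no difference is read from 24 h. Genes of the unfolded protein response were lower in 20 of 22 members with a median of -0.48 (adjusted p = 2.3e-07, and adjusted p = 0.63 with an estimated correlation). Herpud1 stood at 228, 356 and 286 CPM in WT and at 113, 191 and 107 CPM in the KO-labelled libraries. Dnajb9 stood at 31.3, 136 and 57.2 CPM in WT and at 4.97, 33.8 and 34.2 CPM in the KO-labelled libraries, and it is among the 100 expressed genes nearest to Ifrd1. Immediate early genes were lower in 15 of 20 members with a median of -0.75 (adjusted p = 1.6e-05, and adjusted p = 0.63 with an estimated correlation), 0 over all genes and 1 adjusted over the list alone. Their median was 0.00 at 0 h, -0.31 at 12 h and -1.44 at 24 h, and Egr1 and Jun had ratios of 1.39 and 1.67 at 0 h.

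Genes of oxidative phosphorylation were lower in 25 of 27 members with a median of -0.59 (camera adjusted p = 5.9e-06, and adjusted p = 0.63 with an estimated correlation). Mitochondrially encoded and nuclear-retained RNAs moved with them, lower in 10 of 12 members with a median of -0.57 (adjusted p = 0.00057, and adjusted p = 0.63 with an estimated correlation). Markers of other cell types did not pass in this contrast, where erythroid markers had the smallest p (median -1.29, adjusted p = 0.127). Genes that encode hepatocyte ligands for macrophages were higher in 11 and lower in 16 of 27 members with a median of -0.13 (adjusted p = 0.76). Genes of fatty acid oxidation had a median of 0.02 (adjusted p = 0.79) and those of lipogenesis a median of -0.25 (adjusted p = 0.24). Male-biased genes had a median of -0.94 (adjusted p = 0.0022, and adjusted p = 0.78 with an estimated correlation). Glucose metabolism (median 0.34, adjusted p = 0.0069), growth factor signalling (0.33, adjusted p = 0.0245) and bile acid genes (0.45, adjusted p = 0.0294) were higher, and acute phase (-0.30, adjusted p = 0.0294) and p53 target genes (-0.42, adjusted p = 0.0346) lower, each with adjusted p = 0.63 with an estimated correlation. Bile acid genes had a median log2 ratio of -0.34 at 0 h and 0.46 at 24 h, so 0 h went the other way.

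Within single time points, 1 KO-labelled library stood against 1 WT library, and the differences were large in both directions. At 0 h, Mfsd2a, a lipid transporter gene, stood at 81.8 CPM in the KO-labelled library and 1.27 CPM in WT, a ratio of 64.6 (45.8 to 94.2). Alpk1 was 21.0 times and Rad51b 17.1 times higher, followed by Tmem51 (15.4) and Tmem266 (10.8). Lower in the KO-labelled library were Ugt2b38, at 4.91 against 186 CPM, Cyp2c40, at 22.4 against 499 CPM, and Gadd45g, at 35.5 against 606 CPM. Selenbp2 stood at 153 against 2590.0 CPM and Cyp2c69 at 12.5 against 210.1 CPM. Male-biased genes were lower in 12 of 12 members at 0 h with a median log2 ratio of -1.98 (percentile 0), and near 0 at 12 h (-0.05) and 24 h (0.07). Cyp2c40 and Cyp2c69 belong to the fixed list of female-biased liver genes and were lower too, so no loss particular to male-biased genes is read from this.

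At 12 h, G6pc and Slc2a2 were among the genes furthest apart. G6pc, which encodes glucose-6-phosphatase, stood at 50.9 CPM in the KO-labelled library and 2.16 CPM in WT, a ratio of 23.6. The glucose transporter gene Slc2a2 stood at 299.6 against 25.3 CPM, Themis at 57.4 against 1.56 CPM, Aox3 at 1673 against 141 CPM and Apol7a at 50.8 against 4.72 CPM. The leptin receptor gene Lepr stood at 9.37 CPM in the KO-labelled library and 354 CPM in WT, Tead1 at 73.4 against 421 CPM, and the lipogenic gene Thrsp at 34.0 against 187 CPM. Tnfrsf23 stood at 10.7 against 55.6 CPM. Acute phase genes were lower in 23 of 27 members with a median log2 ratio of -0.69 (percentile 0).

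At 24 h, cytochrome P450 genes of the pericentral zone were far higher in the KO-labelled library. Cyp2c54 stood at 323 against 0.962 CPM in WT, a ratio of 335 (254 to 452), and Cyp2c29 at 909 against 9.12 CPM, a ratio of 99.7. Slc22a28 stood at 122 against 0.693 CPM, Ces1d at 165 against 1.89 CPM and Akr1c6 at 1513 against 21.8 CPM. Lower were the calcium channel gene Cacna1b, at 0.442 against 170.2 CPM, and the estrogen sulfotransferase gene Sult1e1, at 0.902 against 281 CPM. Dlgap2 stood at 20.2 against 1071 CPM and Mup17 at 5.16 against 188 CPM. Pericentral genes were higher in 17 of 17 members with a median log2 ratio of 2.48 (percentile 100), and immediate early genes lower in 17 of 17 with a median of -1.44 (percentile 0).

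Genes of the unfolded protein response had median log2 ratios of -0.53 at 0 h, -0.64 at 12 h and -0.48 at 24 h, at percentiles of 0.48, 0 and 0.14 among random lists. Genes of oxidative phosphorylation had medians of -0.65, -0.47 and -0.26, at percentiles of 0.01, 0.01 and 4.31. Genes of cholesterol synthesis had medians of 1.165 at 0 h, 0.67 at 12 h and -0.15 at 24 h. The G1/S genes of DNA replication had medians of -0.23, -0.19 and 0.38. Scaling by TMM in place of total UMIs shifts all log2 ratios by 0.19 at 24 h, while the median of all genes there was -0.16. Outside the central 95% of random lists stood 13 lists at 0 h, 7 at 12 h and 13 at 24 h.

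**Figure D4:**
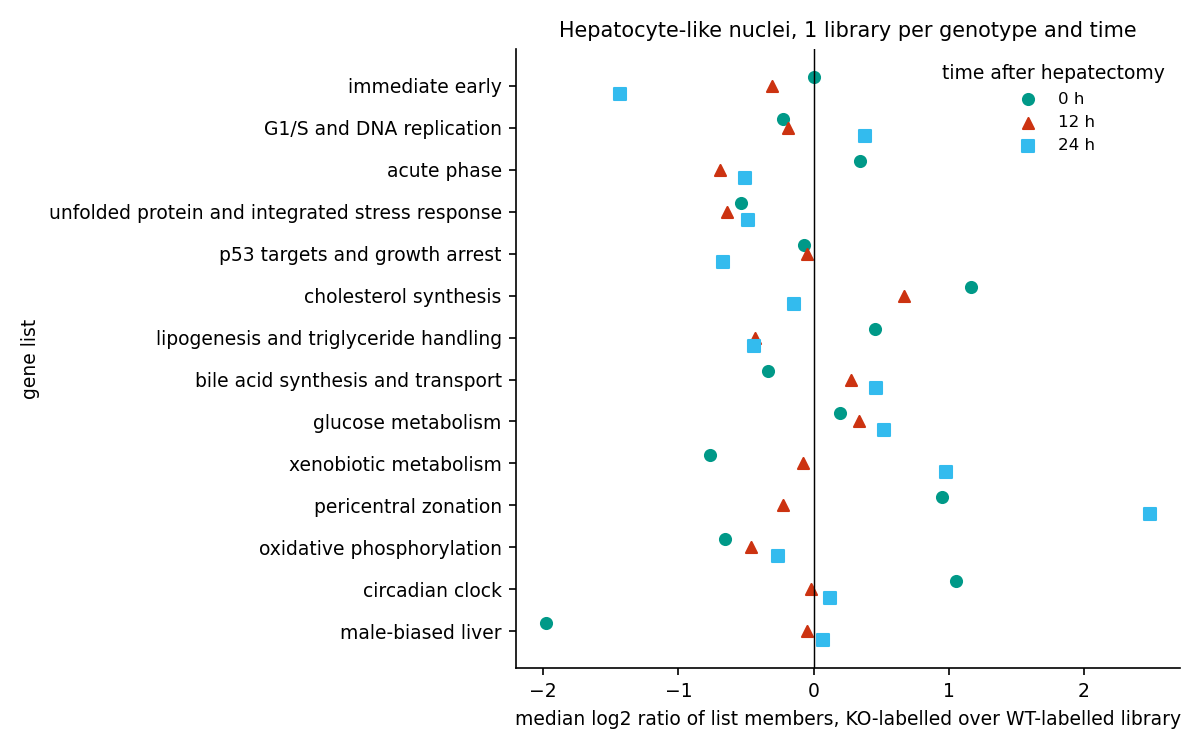
Median log2 ratio of KO-labelled over WT hepatocyte-like nuclei for gene lists along the vertical axis, with 1 symbol for each of 0, 12 and 24 h and no error bars. Pericentral genes lie at 0.95, -0.23 and 2.48, and immediate early genes at 0.00, -0.31 and -1.44.

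In the other classes the genotype comparison asks whether KO-labelled livers differ in the cells around the hepatocytes. In endothelial-like nuclei the chromatin gene Gse1 stood at 124, 70.6 and 209 CPM in WT at 0, 12 and 24 h and at 576, 251 and 458 CPM in the KO-labelled libraries (log2 1.75, SE 0.28, adjusted p = 0.289). Rasgrf2 had a log2 value of 1.75 (adjusted p = 0.289) and Adam12 of 1.97 (adjusted p = 0.412). The lipid droplet gene Hilpda had a value of -2.00 (adjusted p = 0.53), Fosl2 of -1.32 (adjusted p = 0.53) and H3f3b of -0.99 (adjusted p = 0.596). In edgeR 0 of 12034 genes were called, 760.0 had an unadjusted p under 0.05, and DESeq2 called 9 higher and 1 lower. Immediate early genes were lower in 18 of 19 members with a median of -0.70 (camera adjusted p = 2.5e-10, and adjusted p = 0.21 with an estimated correlation), 0 over all genes and 6 adjusted over the list alone. Angiocrine genes were higher in 16 of 25 members (adjusted p = 0.34).

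In macrophage-like nuclei the immunoglobulin gene Igha stood at 0 CPM in WT at every time and at 13.6, 299.8 and 27.5 CPM in the KO-labelled libraries (adjusted p = 0.0763). It is a product of plasma cells. Gfra2 had a log2 value of 1.43 and Tmem117 of 1.08, each with adjusted p = 0.868. The haemoglobin genes Hba-a2 (-2.54, adjusted p = 0.832), Hbb-bs (-2.44) and Hba-a1 (-2.32, adjusted p = 0.868) are products of red cells. In edgeR 0 of 9763 genes were called, 449 had an unadjusted p under 0.05, and DESeq2 called 0 higher and 4 lower. Immediate early genes were lower in 14 of 17 members with a median of -0.80 (camera adjusted p = 2.7e-05, and adjusted p = 0.51 with an estimated correlation). Inflammatory macrophage genes were lower in 11 of 17 members with a median of -0.52 (adjusted p = 0.08), and Kupffer cell genes were higher in 10 of 18 with a median of 0.03 (adjusted p = 0.38). Macrophage receptor genes were higher in 14 and lower in 10 members (adjusted p = 0.55).

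In stellate cell-like nuclei Ankrd55 (log2 1.47), Nmnat2 (1.96) and Pde4a (1.19) were higher and Adamts15 (-1.59) and Igfbp3 (-1.53) lower in the KO-labelled libraries, each with adjusted p = 0.807, as was Hbb-bs (-1.51, adjusted p = 0.899). In edgeR 0 of 10660.0 genes were called, 437 had an unadjusted p under 0.05, and DESeq2 called 1 higher and 0 lower. Immediate early genes were lower in 14 of 17 members with a median of -0.38 (camera adjusted p = 0.0001, and adjusted p = 0.48 with an estimated correlation). Genes of stellate cell activation were higher in 13 and lower in 11 members (adjusted p = 0.61). RNA of hepatocytes was present in all these classes. The median hepatocyte marker stood in endothelial-like nuclei at 27.9% to 60.4% of its hepatocyte level, and in macrophage-like nuclei at 20.3% to 42.1%.

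The shares of nuclei show how the make-up of the libraries differed. Hepatocyte-like nuclei made up 54.5% of WT and 57.7% of KO-labelled nuclei at 0 h, 80.5% and 74.9% at 12 h, and 56.4% and 57.6% at 24 h. Macrophage-like nuclei made up 4.56% (4.17 to 4.99) of WT and 6.49% (6.01 to 6.9998) of KO-labelled nuclei at 0 h, a difference of 1.93 points that turned to -0.267 with at least 1000 genes per nucleus. At 12 h they made up 1.67% (1.45 to 1.91) and 4.04% (3.65 to 4.45), and at 24 h 6.18% (5.67 to 6.73) and 5.94% (5.49 to 6.42). Neutrophil-like nuclei at 24 h made up 2.14% (1.84 to 2.48) in WT and 0.483% (0.357 to 0.638) in the KO-labelled library. Cluster 13, led by the monocyte genes F13a1, Chil3, Ccr2 and Vcan, made up 4.61% (4.16 to 5.09) and 1.72% (1.48 to 1.996) at 24 h. Endothelial-like nuclei made up 23.2% and 17.8% at 0 h, 7.96% and 11.1% at 12 h, and 19.1% and 17.6% at 24 h. These shares depend on the clustering. At Leiden resolution 0.5 the endothelial-like cluster held 0 and 4 nuclei at 12 h and 2 and 37 at 24 h, doublets included. An unnamed cluster then held 1475 and 1404 at 12 h and 1892 and 1785 at 24 h, with endothelial markers scored best. At resolution 2 an unnamed cluster held 1276 and 929 nuclei at 12 h. A paired exact permutation test over 3 time points cannot give a p below 0.25, so none is given.

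**Figure D5:**
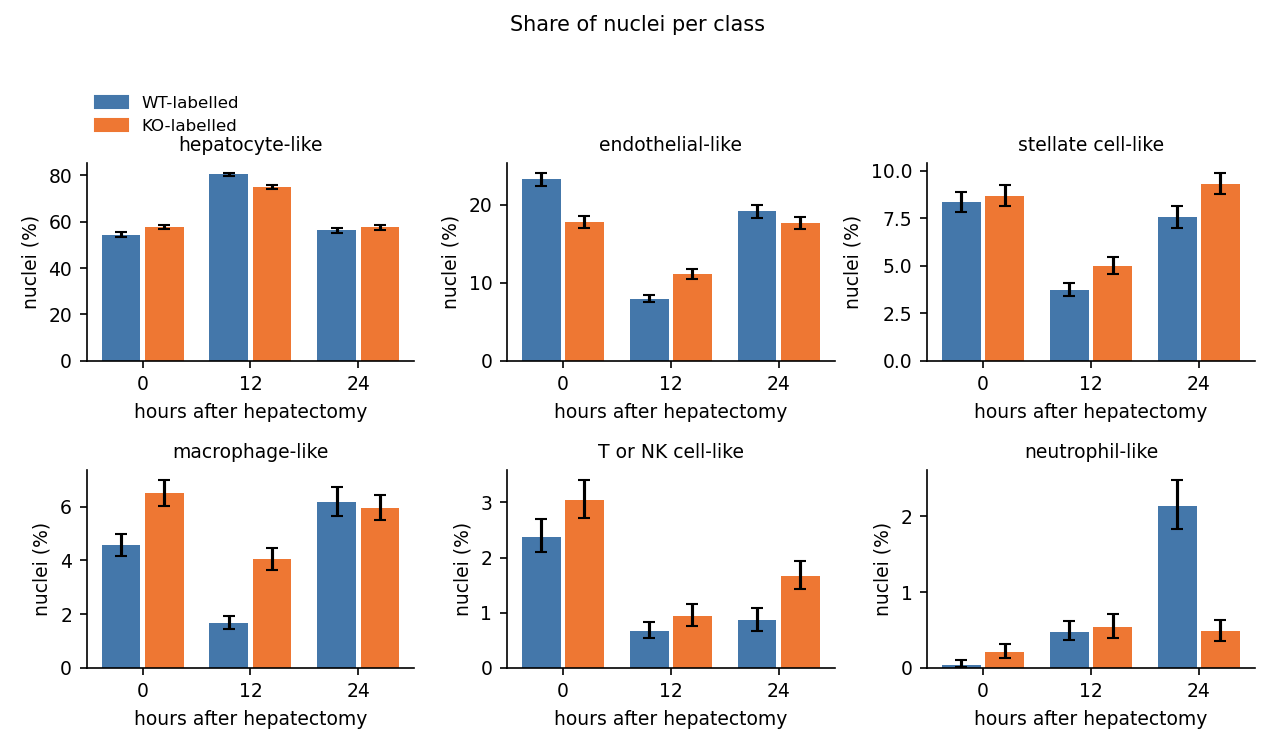
Share of nuclei in each class per library in percent, with exact Clopper-Pearson intervals as bars and genotype by colour along time after surgery. Macrophage-like nuclei made up 1.67% in WT and 4.04% in the KO-labelled library at 12 h.

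Cycling hepatocyte nuclei were sought as a measure of regrowth. After thinning to 1500 UMIs, 0.549% of hepatocyte-like nuclei in WT and 0.389% in the KO-labelled library at 0 h had at least 2 UMIs in genes of G2 and mitosis. At 12 h the shares were 0.995% and 0.438%, and at 24 h 3.41% (2.90 to 3.98) and 3.23% (2.79 to 3.72). Without thinning, 34.2% of WT and 20.4% of KO-labelled nuclei met the same criterion at 24 h. Stellate cell-like nuclei at 24 h gave 3.199% (1.94 to 4.95) and 2.40% (1.49 to 3.65) after thinning, close to the shares in hepatocytes, so no number of dividing hepatocytes is drawn from these shares. The summed CPM of the list in hepatocyte-like nuclei was 60.5 and 53.02 at 0 h, 85.9 and 50.8 at 12 h, and 136 and 143 at 24 h.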

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

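The matching of nuclei in depth, the search for the partner of a swapped label, the comparison of DNA replication genes before it and the criterion that picked out gene lists of opposite sign are tests chosen only after the results had been seen.

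In hepatocyte-like nuclei, 3 gene lists had a median log2 ratio of KO-labelled over WT of opposite sign at different times, each at least 0.25 from 0 and outside the central 95% of matched random lists. Genes of lipogenesis and triglyceride handling had a median of 0.46 at 0 h, against -0.43 at 12 h and -0.44 at 24 h, with 19 of 31 members higher at 0 h and 22 of 31 lower at both later times. Genes of bile acid synthesis and transport had a median of -0.34 at 0 h and 0.46 at 24 h. Genes of xenobiotic metabolism had a median of -0.77 at 0 h and 0.98 at 24 h, where Cyp2c54 and Cyp2c29 were among the genes furthest apart. The signs were the same with TMM scaling. With 1 library per group, the difference between time points was not tested.

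Hepatocyte-like nuclei of the 24 h KO-labelled library lay at 0.438 (0.414 to 0.462) of the way from the mean of the 0 h libraries to the 24 h WT library over 6875 genes (interval over resampled genes), while the 12 h libraries lay at 0.945 (WT) and 0.882 (KO-labelled), and each 0 h library taken from the other one lay at 0.3001 (WT) and 0.339 (KO-labelled). A difference in depth is argued against, since the position was 0.452 (0.428 to 0.476) over 898 nuclei per library matched in UMIs. A mixture of nuclei in 0 h-like and 24 h-like states is argued against as well, since the SD of a single-nucleus score was 0.565 (0.554 to 0.579), where 2.82 would be needed by a mixture and 0.571 without mixing. For a label swapped with a 0 h library, no partner looked out of place. At 31.1% (25.9 to 36.7) of 302 genes the 0 h WT library lay nearer to the other 3 later libraries than to the other 0 h library. For the 0 h KO-labelled library this held at 21.5% (16.6 to 26.9) of 261 genes. These shares cannot decide on a swap, since the 0 h libraries have a library series and gene list in common that could also hold them together. Earlier tests by DNA replication genes and by position had decided nothing either. A wrong label without a swap or a sample from outside the series was not tested, and a biological difference between genotypes stays open and was not tested.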

How the results depend on the processing

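Alternatives chosen after seeing the data were the genotype contrast without the 24 h or 0 h KO-labelled library, 0 to 12 h without the 24 h KO-labelled or both 24 h libraries, 12 to 24 h without both 0 h libraries, and other list tests in the classes besides hepatocytes. The cause was not tested for any change of a count or share given here.

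For genotype in hepatocytes edgeR called 0 genes (1106 at an unadjusted p under 0.05), against 10 without a filter on low counts, 187 with DESeq2, 0 to 14 when a pair of libraries was left out, 51 without the 24 h KO-labelled library and 0 without the 0 h KO-labelled library. In endothelial-like nuclei the count of 0 (unadjusted 760.0) became 97 without the filter, 10 with DESeq2, 1 to 76 without a pair, 7 without the 24 h and 2 without the 0 h KO-labelled library. In macrophage-like nuclei 0 (unadjusted 449) became 36, 4, 0 to 24 and, without the 24 h KO-labelled library, 18. In stellate cell-like nuclei 0 (unadjusted 437) became 58, 1, 0 to 7, and 2 without either KO-labelled library.

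From 0 to 12 h, the 382 genes became 1376 without the filter on low counts, 2805 with DESeq2, 0 without the genotype term and 0 to 217 when 1 library of these times was left out. The 0 came without the 0 h WT library and without the 12 h KO-labelled library, with 217 without the 0 h KO-labelled and 116 without the 12 h WT library. The count was 1899 without both 24 h libraries and 2319 without the 24 h KO-labelled library. All 382 genes were called with DESeq2 and in both of these last fits. From 0 to 24 h, 0 (unadjusted 2269) became 200 without the filter, 924 with DESeq2 and 0 to 856 without 1 library, 856 without the 24 h KO-labelled and 73 without the 24 h WT library. From 12 to 24 h, 0 (unadjusted 1479) became 66, 403 and 0 to 287, with 287 without the 24 h WT, 107 without the 24 h KO-labelled and 1 without the 12 h KO-labelled library. Without both 0 h libraries it was 0. A time left with 1 library is assumed to vary like the other groups. DESeq2 size factors in edgeR, the filters on nuclei and keeping doublets left each of the hepatocyte counts within 1.5 times.

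Gene lists depended on the correlation assumed. In hepatocytes camera called 12 lists for genotype, 10 from 0 to 12 h, 13 from 0 to 24 h and 15 from 12 to 24 h, and 0 in each with an estimated correlation or with fry. The counts of 2 in endothelial-like and 1 in stellate cell-like nuclei became 0 in both ways, and the 1 in macrophage-like nuclei, immediate early genes lower, became 0 with an estimated correlation. Fry called another list there, with genes of G2 and mitosis higher. No paired analysis was possible beyond the time term, because each genotype had 1 library per time point.

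The share of hepatocyte-like nuclei, KO-labelled minus WT, was 3.25 points at 0 h, 10.4 with at least 1000 genes per nucleus and 0.197 with at most 2% mitochondrial UMIs. At 12 h it was -5.55 points and -7.20 with at least 1000 genes, and at 24 h 1.29 points and 11.3 at Leiden resolution 2. At that resolution clusters 43 and 44, scored best for hepatocyte markers, stayed unnamed. They held 339 and 479 nuclei of the 24 h WT library and 0 of the 24 h KO-labelled library, doublets included. The macrophage-like share reversed at 0 h, from 1.93 points to -0.267 with at least 1000 genes, and was 5.24 at resolution 2. There a cluster led by the macrophage genes Clec4f and C1qc stayed unnamed, with 404 WT and 46 KO-labelled nuclei at 0 h. At 24 h the macrophage-like share differed by -0.244 points, -1.27 with at least 1000 genes and 0.507 at resolution 0.5. The share of cycling hepatocyte nuclei at 0 h was -0.160 points, -1.12 with at least 1 UMI and -2.28 unthinned. At 12 h it was -0.557 points, -4.24 with at least 1 UMI, -0.132 with at least 3 and -4.31 unthinned. At 24 h it was -0.175 points, -3.75 with at least 1 UMI, 0.533 with at least 3 and -13.8 unthinned.

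Ifrd1 kept its direction and stayed short of the threshold for genotype in hepatocytes in 12 of 12 settings. Named genes kept direction and side of the threshold in 525 of 694 settings and gene lists in 312 of 426. Ratios within a time point moved by less than the mean log2 distance from the ratio to its interval's bounds in 52 of 60. List medians moved by less than the SD of the matched random lists in 135 of 156. No gene or list past its threshold changed sign. Short of it, from 12 to 24 h, Ifrd1 went from -0.17 to 0.06 without the 24 h KO-labelled library and Ifrd2 from -0.23 to 0.24 without the 24 h WT library. With TMM factors the list medians at 24 h went from -0.15 to 0.03 for fatty acid oxidation, from -0.15 to 0.04 for cholesterol synthesis and from -0.10 to 0.08 for amino acid metabolism. In hepatocyte-like nuclei the smallest sum was that of the 0 h KO-labelled library, with 17708354 UMIs. In the other classes tested it was that of the 12 h WT library, with 1472492 UMIs in endothelial-like, 370964 in macrophage-like and 908955 in stellate cell-like nuclei.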

Other observations

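The tests of exchanged 0 h labels by Ifrd1, of the immunoglobulin constant region, of RNA from other cells in hepatocyte nuclei and of other splits of the libraries are tests chosen only after the results had been seen.

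Genes were also called between time points in the classes around the hepatocytes, in contrasts outside the planned ones. In endothelial-like nuclei from 0 to 12 h, the chemokine gene Cxcl10 fell by 4.94 on the log2 scale (edgeR adjusted p = 0.00311), Gna14 by 5.39 (adjusted p = 0.00151) and Csmd1 by 5.68 (adjusted p = 0.00982), while Apcdd1 rose by 7.40 (adjusted p = 0.017) and Gprc5b by 6.72 (adjusted p = 0.014). Saa2 rose by 7.39 (adjusted p = 0.00151), and it stood at a mean of 2086 CPM in hepatocyte-like nuclei, whose RNA is present in this class. By 24 h Cxcl9 stood lower than at 0 h by a log2 value of -5.07 (adjusted p = 0.00433). In all, 541 genes rose and 659 fell by 12 h, and the count of 1200.0 was 546 with at least 1000 genes per nucleus, 672 without the genotype term, 1253 with DESeq2 and 2060.0 without the filter on low counts. Immediate early genes were higher at 12 h in 18 of 19 members (median 0.94, camera adjusted p = 5.0e-05, and adjusted p = 0.15 with an estimated correlation) and lower from 12 to 24 h in 19 of 19 (median -1.06, adjusted p = 5.3e-11, and adjusted p = 0.17 with an estimated correlation). Hepatocyte marker transcripts in this class rose and fell as well. Their median share of the hepatocyte CPM was 27.9%, 60.4% and 30.6% in WT at 0, 12 and 24 h. In the KO-labelled libraries it was 28.1%, 48.9% and 40.2%. A part of such RNA in these changes was not tested. Endothelial-like nuclei of 0 and 12 h lay in different clusters (WT first, doublets included). Cluster 2 held 2349 and 1694 at 0 h and 0 and 5 at 12 h. Cluster 20 held 63 and 41 at 0 h and 1018 and 1061 at 12 h. At the lower Leiden resolution, the endothelial-like cluster held 0 and 4 at 12 h and an unnamed one 1475 and 1404. At the higher one, an unnamed cluster held 1276 and 929 at 12 h and an endothelial-like one 192 and 457. Genes were not tested at either resolution.

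In macrophage-like nuclei from 0 to 12 h, the chemokine gene Ccl9 rose by 4.88 (adjusted p = 0.00743) and Glis3 by 5.12 (adjusted p = 0.00624), and the interferon-induced gene Gbp2b fell by 3.97 (adjusted p = 0.00733). From 12 to 24 h Lepr fell by 4.65 (adjusted p = 0.0279), from 1264 CPM in WT and 692 CPM in the KO-labelled library to 36.3 and 42.5 CPM. Kupffer cell genes were lower at 12 h in 15 of 18 members (median -0.64, camera adjusted p = 0.0012, and adjusted p = 0.49 with an estimated correlation). Hepatocyte marker transcripts in this class stood at a median of 21.1% of their hepatocyte CPM in WT and 20.3% in the KO-labelled library at 0 h and at 42.1% and 31.1% at 12 h, and dilution of Kupffer cell genes by such RNA was not tested. By 12 h 96 genes rose and 79 fell, a count of 175 that was 95 without the 0 h WT library, 117 with at least 1000 genes per nucleus, 308 with DESeq2, 785 without the filter on low counts, 682 without the 24 h KO-labelled library and 699 without both 24 h libraries. Stellate cell-like nuclei also lay in different clusters, with WT given first and doublets included. Cluster 3 held 876 and 865 at 0 h and 0 at 12 h, and cluster 16 held 6 and 15 at 0 h and 460 and 477 at 12 h. At Leiden resolution 0.5 the stellate cell-like cluster held 4 and 1 nuclei at 12 h, and an unnamed cluster scored best for stellate markers held 794 and 694. In stellate cell-like nuclei the cell cycle inhibitor gene Cdkn1a rose by 7.74 (adjusted p = 0.015) and the metallothionein gene Mt2 by 6.66 (adjusted p = 0.00696), and Grin2b fell by 7.07 (adjusted p = 0.0112) by 12 h. Mt2 stood there at 1636 and 941 CPM at 12 h in WT and KO-labelled libraries, against 1021 and 489 CPM in hepatocyte-like nuclei. Hepatocyte marker transcripts in the stellate class stood at a median of 43.3% and 31.95% of their hepatocyte CPM at 12 h, up from 22.0% and 27.4% at 0 h. Of 267 genes called there, 107 rose and 160.0 fell, and the count fell to 27 with at least 1000 genes per nucleus. It was 502 with DESeq2, 1181 without the filter on low counts, 840.0 without the 0 h, 121 without the 12 h and 927 without the 24 h KO-labelled library. Time and library series cannot be told apart in the contrasts with 0 h.

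Ifrd1 in hepatocyte-like nuclei of the 0 h KO-labelled library was not below WT. An exchange of the 0 h labels cannot be told apart from correct labels by Ifrd1, since its ratio with exchanged labels would be 0.986 (0.936 to 1.04), as near to 1 as the ratio seen. Another test of that exchange decided nothing. Of 148 genes at least 2-fold apart in the same direction at 12 and 24 h, 84 had that direction at 0 h, 56.8% (48.4 to 64.9), with 72 of 113 higher genes and 12 of 35 lower genes. UMIs counted outside the deleted part of the gene stay open as a candidate explanation, since the 24042 Ifrd1 UMIs in hepatocyte-like nuclei of the KO-labelled libraries carry no positions, and a wrong animal or an outside sample at 0 h was not tested.

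Jchain, a plasma cell transcript, was higher in B or plasma cell-like nuclei of all 3 KO-labelled libraries. A biological difference between genotypes stays open and untested. In cluster 13 the Igkc ratio of KO-labelled over WT was 3.97 at 0 h, 0.0425 at 12 h and 2332 at 24 h, so 12 h went the other way. Clusters 8 and 12, with immunoglobulin genes among their leading genes, were set aside as mixed and enter none of the counts below. In B or plasma cell-like nuclei 1744 Jchain UMIs stood against 8 in WT at 0 h, 369 against 62 at 12 h and 2533 against 0 at 24 h. The KO-labelled and WT libraries held 237 and 205 such nuclei at 0 h, 36 and 37 at 12 h, and 79 and 16 at 24 h. All UMIs of the class at 24 h numbered 216225 and 19397. In hepatocyte-like nuclei the Jchain ratio of KO-labelled over WT was only 1.75 (1.31 to 2.34) at 0 h, and it was 4.74 at 12 h and 90.9 at 24 h. The 0 h WT library thus held Jchain RNA outside the B or plasma cell-like class. As the only source of the difference in B or plasma cell-like nuclei at 0 h, a variant of the immunoglobulin constant region genes is argued against. Jchain lies outside these genes, and the lower bound of its ratio was 99.7 at 0 h. The bound was 61.6 at 24 h, where WT held 16 such nuclei, and 3.46 at 12 h. All these bounds cover counting error only. Whether the constant region genes differ as well was not tested. Jchain and Ighg2c together held 8, 62 and 0 UMIs in WT, as many as Jchain alone. In the KO-labelled libraries they held 2510, 1470 and 5390. At 12 h just 6 KO-labelled nuclei and 1 WT nucleus held at least 10 Jchain or Ighg2c UMIs, so that time point cannot decide. A single nucleus per library is argued against too, since the nucleus with the most held a median of 22.2% of Jchain and Ighg2c UMIs, although it held 85.1% at 12 h. In hepatocyte-like nuclei of the KO-labelled libraries the Igkc to Jchain ratio differed from that of B or plasma cell-like nuclei by a median of 1.10-fold, which is consistent with RNA from other cells, but at 24 h the fold was 1.46 and the interval (12.0 to 14.1) excluded the plasma cell value of 8.90.

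Genes next to Ifrd1 may carry strain variants linked to the targeted locus, as a hypothesis. Of the 100 expressed genes nearest to Ifrd1, 4.0% (1.10 to 9.93) were at least 1.5-fold apart in the same direction at all 3 times, namely Ahr, Arl4a, Dnajb9 and Egln3, against 3.01% of 10415 others, so strain variants cannot be told apart from the background by this test.

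The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. The real genotype split called 0 genes in hepatocyte-like nuclei (edgeR, 1106 at an unadjusted p under 0.05, 187 by DESeq2) and the highest other split 0. In endothelial-like nuclei the real split called 0 (unadjusted 760.0, DESeq2 10) and the highest other 12, in macrophage-like nuclei 0 (unadjusted 449, DESeq2 4) and 14, and in stellate cell-like nuclei 0 (unadjusted 437, DESeq2 1) and 16. The highest counts in these 3 classes came from the splits that put both 0 h libraries with 1 of the 24 h libraries. With time in the model, such a split rests on the 24 h pair alone.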
